A study of Mus musculus with 12 samples.

How the data were processed

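RNA from cultured mouse cortical neurons was measured in 12 libraries, which hold 5 groups of 2 biological replicates. Replicate 1 of shAdar2 had 3 technical libraries prepared from RNA of the same neurons, per the labels, and their counts were summed to 1 sample, which left 10 samples. Per the labels' protocols, neurons were dissociated at embryonic day 16.5, infected with lentivirus carrying an shRNA the day after seeding, and harvested 7 days after dissection. Ribosomal RNA was removed from 250 ng of RNA with DNA oligonucleotides antisense to human ribosomal RNA and RNase H before library construction. Transcripts without a poly(A) tail are therefore retained.

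The authors deposited, for each library, a gene table of RSEM expected counts (estimated reads per gene, not normalised) and a table of editing sites. Per the file headers, each site has deposited counts of reads with the unedited base (A) and the edited base (G), and an editing level as a fraction, which equalled G/(A+G) within rounding. Trim Galore 0.4.5, STAR 2.5.4b, SAMtools 1.4, RSEM 1.2.30 and DESeq2 1.20.0 are named with the mm9 build in the submitters' processing notes, with no role or order. How sites were chosen and how reads at sites were filtered is not given in the sources used here. Site positions are given on mm9. The annotation at hand was GENCODE M21 on GRCm38, so sites were not assigned to genes here. Sites at most 10 kb apart were joined into clusters (13301 clusters from 46689 sites), which took the place of genes wherever a rule or a permutation needed them.

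Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr, which left 14785, normalised with TMM and tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test over all 10 samples, which share 1 estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was taken from the fold change and its F statistic. Levels are given as TMM-normalised CPM (counts scaled to a common library size), mean ± SD of 2 samples. Edited and unedited reads per site were tested with the same quasi-likelihood test in the 4 samples of each comparison, with a coefficient per library for coverage, at sites with at least 20 reads in each sample and at least 5 edited and 5 unedited reads in all. Overlaps of site lists were tested with two-sided Fisher's exact tests. Where 2 comparisons shared control samples neither that test nor 100 simulations of unchanged groups, which make almost no calls, was used here. Floors cover counting error only, since the reads carry no molecular identifiers. The interval of the slope between changes in editing comes from 10000 bootstrap draws of clusters.

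A total of 26 gene lists, the tests and the rule for named genes and sites were fixed before the data were examined. The list of mitochondrially encoded transcripts had no tested member. Lists were tested with camera (limma 3.58.1) with an inter-gene correlation of 0.01 and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it, and no call of camera held at an adjusted p under 0.05 with an estimated correlation. The rule for named genes took (a) Adar, Adarb1, Adarb2 and Zfr, (b) the 8 genes with the largest increase and the 8 with the largest decrease among those called, with at least 5 CPM in the higher group and no overlap between the groups, and (c) up to 4 members with the lowest p from a list with a camera call or at least 3 called members, and up to 2 from other lists. All genes of parts a and b are named, and examples from part c. Results of 2 genes that the rule took are not reported here. For sites the rule took the 6 largest decreases and the 4 largest increases, with at most 2 per cluster, or fewer where fewer were called.

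The gene test was checked on 5 simulated sets per comparison with 200 genes changed. It recovered 56.8%, 53.9% and 54.6% of the genes changed by 2-fold and 81.5%, 85.6% and 86.0% of those changed by 4-fold for the shAdar1, shAdar2 and shZfr comparisons, and 4.76%, 6.01% and 5.08% of its calls were false. Each simulated gene had the same spread in all groups, so these rates do not cover groups that differ in spread. The site test was checked on 10 sets per comparison. It recovered 14.0%, 72.0% and 49.9% of sites whose odds changed by 4-fold, and 2.96%, 9.57% and 3.14% of its calls were false, so smaller changes in editing were largely below detection.

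Alternatives covered DESeq2 (1.42.0) and its size factors, no filter on low counts, only the compared groups in a fit, a replicate block, each replicate left out, other coverage minimums, Fisher's exact test on pooled reads, and single technical libraries. The other control hairpin, both control hairpins pooled, the 2 shZfr samples summed to 1, Rn45s left out and the deepest site left out were added after seeing the data. Words of 7 bases in the longest annotated 3' UTR of each gene (GENCODE M21) were counted against genes of like UTR length with a Python 3.11.15 program. The same search in 40 simulated sets of 422 genes recovered the planted word in 100% of them, and 22.5% of random sets reached a standardised excess of 5. Figures were drawn with matplotlib 3.10.9.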

Results

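RNA editing and gene expression were measured in primary cortical neurons of C57BL/6J mouse embryos after lentiviral short hairpin RNAs (shRNAs) had been used to lower the editing enzymes or the RNA-binding protein Zfr. ADAR enzymes convert adenosine to inosine in double-stranded RNA. Inosine is read as guanosine, so the share of reads with G at a site is its editing level. Adar encodes ADAR1, Adarb1 encodes ADAR2, Adarb2 encodes a family member without known catalytic activity, and Zfr encodes a zinc finger protein with a DZF domain. There were 5 groups of 2 biological replicates: control hairpins shControl1 and shControl2, and hairpins shAdar1, shAdar2 and shZfr. Libraries held 1.58e+07 to 2.97e+07 expected counts, and reads at listed editing sites ranged from 110255 in shAdar2 replicate 2 to 676955 in shZfr replicate 2.

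Each hairpin lowered its target. Adar fell in shAdar1 to 53.3 ± 2.43 CPM from 172.2 ± 27.6 CPM in shControl1, which left 30.9% (log2 fold change −1.69 ± 0.13 SE, edgeR adjusted p = 0.00034, n = 2 per group). Adarb1 fell in shAdar2 to 50.2 ± 2.53 CPM from 120.4 ± 2.77 CPM, which left 41.7% (−1.26 ± 0.12, adjusted p = 7.12e-05). Zfr fell in shZfr to 172.6 ± 0.118 CPM from 458.8 ± 52.6 CPM in shControl2, which left 37.6% (−1.41 ± 0.11, adjusted p = 6.36e-05). Zfr was at 278.8 ± 15.6 CPM in shControl1, so its fall is smaller against that control, and at 188.2 ± 12.6 CPM in shAdar2. Adarb1 also fell in shZfr, to 47.3 ± 2.62 CPM from 95.7 ± 5.25 CPM (−1.02 ± 0.12, adjusted p = 0.00038), and it was lower in shZfr than in shControl1 too (−1.35 ± 0.12, adjusted p = 4.0e-05). Zfr fell in shAdar2 (−0.57 ± 0.11, adjusted p = 0.0029), and Adarb2 passed the test there by little (0.70 ± 0.26, adjusted p = 0.049), on technical libraries of replicate 1 at 154.5, 54.3 and 145.2 CPM with replicate 2 at 69.9 CPM, and not against shControl2 (0.15 ± 0.26, adjusted p = 0.646). Adar in shZfr (0.09 ± 0.13, adjusted p = 0.66), Adar in shAdar2 (0.20 ± 0.13, adjusted p = 0.23) and Adarb1 in shAdar1 (−0.18 ± 0.12, adjusted p = 0.34) did not pass the test.

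**Figure D1:**
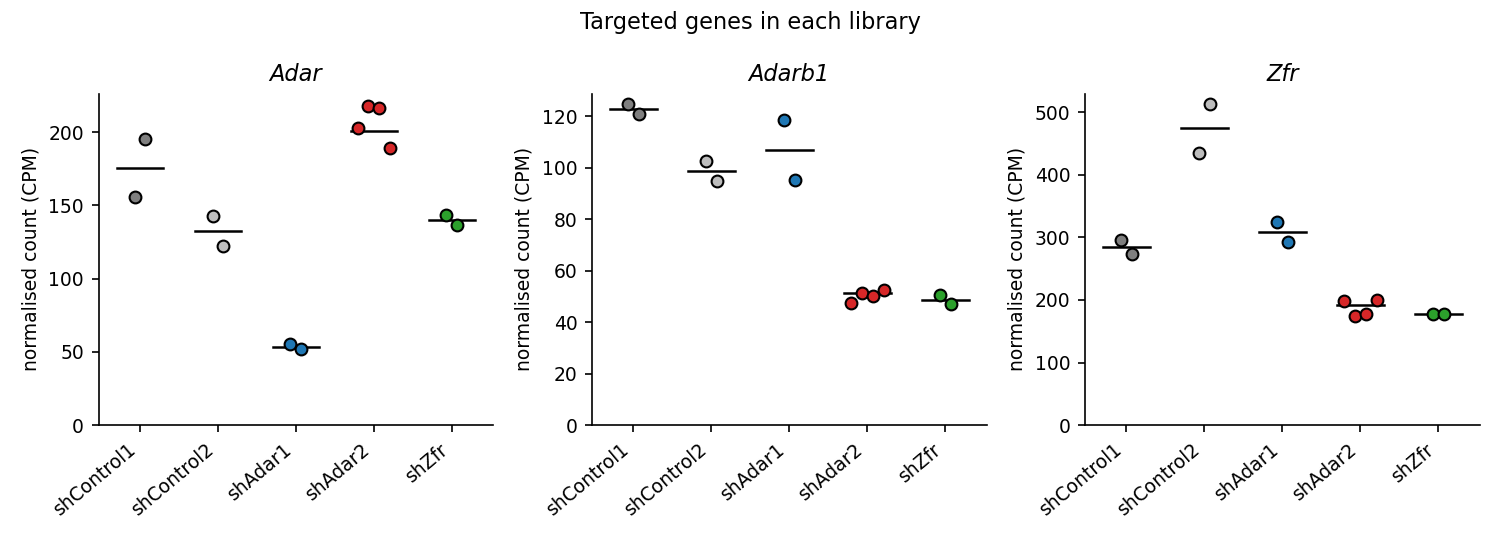
Normalised level (CPM) of Adar, Adarb1 and Zfr in each of the 12 libraries, by group. The line is the group mean over biological replicates, with technical libraries averaged first. Adar was lowest in shAdar1, Adarb1 was low in both shAdar2 and shZfr, and Zfr differed between the control hairpins.

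The control hairpins, each of which serves as the baseline of different comparisons, gave cultures that differed from each other. In shControl2 the p53 target genes were lower, with 11 of 19 past the test (13 adjusted over the list alone, where 1 was higher) and a median log2 fold change of −1.17. Astrocyte markers were higher, with 10 of 14 past the test (11 over the list alone) and a median of 1.34, as were 5 of 9 oligodendrocyte lineage markers (7 over the list alone, median 2.03) and 8 of 14 markers of proliferating progenitors (8 over the list alone, median 1.09). Genes of splicing and neuronal RNA-binding proteins were higher at 20 of 35 and lower at 1 (20 and 2 adjusted over the list alone, median 0.44), and excitatory cortical neuron markers at 8 of 15 (10 over the list alone, median 0.54). Zfr was higher (0.72 ± 0.11, adjusted p = 0.00089), and Adar (−0.42 ± 0.13, adjusted p = 0.025) and Adarb1 (−0.33 ± 0.12, adjusted p = 0.046) were lower in shControl2. By camera the adjusted p was 0.000632 for the p53 and the astrocyte lists, 0.00624 for the oligodendrocyte list, 0.014 for the progenitor list, 0.000144 for the splicing list and 0.00238 for the excitatory list. With an estimated correlation the adjusted p was 0.255 for the p53, splicing and excitatory lists, 0.697 for the astrocyte and oligodendrocyte lists and 0.861 for the progenitor list. In all, 2937 genes were higher and 3430 lower in shControl2 than in shControl1, and without 1 control sample 3574 to 5163 genes differed, against 6367. Editing was lower in shControl2 at 82 of 989 tested sites, the only sites past the test, and the mean level over the tested sites was 12.2% ± 0.546 against 18.7% ± 0.149 in shControl1. The median change at these sites was −18.9 percentage points. With any 1 of the 4 control samples left out it was −17.5 to −20.5, and hardly any of these calls remained. Among genes lower in shControl2 than in every other group, 68 of 668 held the 7-base word TCCCGTT in the 3' UTR against 14.9 expected, and among those lower in shControl1, 117 of 422 held TAATGAT against 57.2 expected.

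To find the sites that depend on ADAR1, shAdar1 was compared with shControl1. Editing fell widely: 299 of 890 tested sites, in 179 clusters, were edited less in shAdar1, and 3 were edited more. The mean level over the tested sites was 8.64% ± 0.900 in shAdar1 against 19.3% ± 0.0536 in shControl1. The site at chromosome 17, position 24315298 went from 76.2% ± 8.73 (64 reads over 2 samples) to 2.08% ± 2.95 (46 reads), with an adjusted p of 2.82e-05, and stood at 44.8% ± 7.37 in shControl2. Chromosome 5, position 125936975 went from 72.2% ± 1.61 (181 reads) to 5.40% ± 2.35 (192 reads), with an adjusted p of 2.22e-06, and stood at 53.2% ± 2.77 in shControl2. The next largest decreases were at chromosome 3, position 96436383 (75% to 1.22%), chromosome 11, position 116442451 (74.4% to 2.00%), and chromosome 14, positions 125016066 (85.3% to 14.3%) and 124885339 (94.5% to 26.4%). The 3 increases were 13.0 percentage points at chromosome 2, position 29767553, 9.59 at chromosome 2, position 157383896, and 1.62 at chromosome X, position 147420046, and each needed all 4 samples to pass. The count of decreased sites was 35 without shAdar1 replicate 2 and 166, 168 and 170 without shAdar1 replicate 1, shControl1 replicate 2 and shControl1 replicate 1. Against shControl2, 135 sites were decreased, and of 616 sites tested against both controls 208 were decreased against shControl1 and 93 against both.

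**Figure D2:**
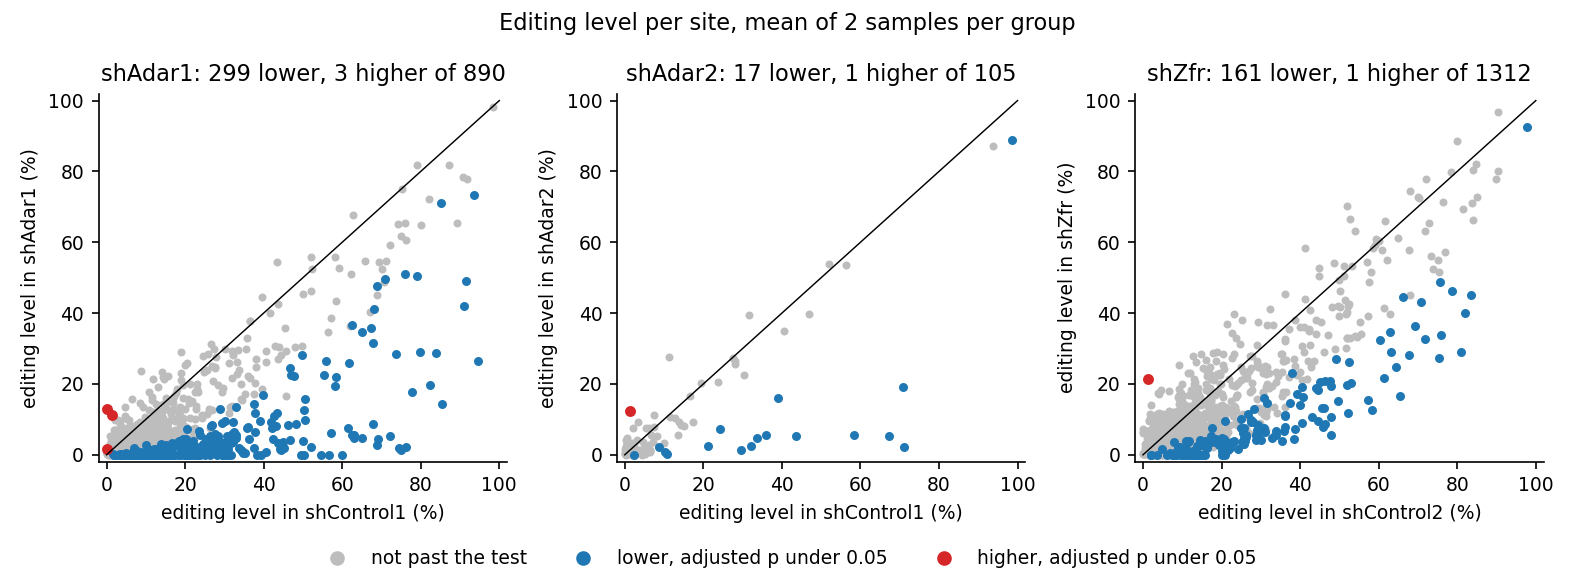
Editing level in percent per tested site, mean of 2 samples, in each knockdown group (vertical axis) against its control (horizontal axis), with the line of equal levels. Sites past the test lie below the line except 3 in shAdar1, 1 in shAdar2 and 1 in shZfr.

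In gene expression, shAdar1 neurons had fewer transcripts of p53 target genes and of some GABA type A receptor subunits than shControl1 neurons, and more of splicing factors, cholesterol enzymes and astrocyte markers. Of the 19 p53 targets 12 fell (14 adjusted over the list alone, where 1 rose), with a median log2 fold change of −1.24. Examples are the cell cycle inhibitor Cdkn1a (−1.56 ± 0.16), the apoptosis gene Bbc3 (−1.54 ± 0.19), Phlda3 (−1.73 ± 0.17) and Sesn2 (−1.34 ± 0.15). The camera adjusted p was 1.23e-07, and 0.243 with an estimated correlation. Against shControl2 the direction turned: the list had a median of 0.18, and Cdkn1a stood at 0.18 ± 0.16, Bbc3 at 0.21 ± 0.20, Phlda3 at 0.31 ± 0.18 and Sesn2 at 0.30 ± 0.15. The GABA and glycine receptor subunits Gabra4 (−0.76 ± 0.13) and Gabrb2 (−0.63 ± 0.10) fell, and also fell against shControl2 (−0.86 ± 0.13 and −0.62 ± 0.10). In that list 3 of 16 fell and 1 rose, the same numbers adjusted over the list alone, with a camera adjusted p of 0.0287 and of 0.702 with an estimated correlation.

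Among splicing and neuronal RNA-binding proteins 11 of 35 rose and 1 fell (16 and 1 adjusted over the list alone, median 0.32). They included the cold-inducible Rbm3 (1.23 ± 0.09) and Rbfox2 (0.78 ± 0.10). Cholesterol biosynthesis genes rose at 5 of 20 (10 over the list alone, median 0.61), among them Sqle (1.05 ± 0.26) and Mvk (1.07 ± 0.28). Astrocyte markers rose at 5 of 14 (6 over the list alone, median 1.09), among them Aldoc (2.29 ± 0.42) and Aldh1l1 (1.56 ± 0.37), and replication-dependent histone genes rose at 5 of 16 (7 over the list alone, median 0.82). Markers of proliferating progenitors rose at 2 of 14 (5 over the list alone, median 0.99), and immediate early genes fell at 3 of 18 (9 over the list alone, median −1.82). The 2 shAdar1 samples differed by a median log2 of −0.958 (replicate 1 minus 2) over 37 astrocyte, oligodendrocyte lineage and progenitor markers. The camera adjusted p was 1.3e-06 for splicing, 0.000149 for cholesterol, 0.00115 for astrocytes, 0.00114 for histones, 0.0346 for progenitors and 0.0246 for immediate early genes. With an estimated correlation it was 0.296 for splicing, 0.702 for cholesterol, astrocytes and histones, 0.735 for progenitors and 0.755 for immediate early genes. Against shControl2 the medians turned to −0.04 for splicing, −0.20 for astrocytes, −0.25 for progenitors and 0.35 for immediate early genes, which were lower in shControl2 than in shControl1 too at 10 of 18 (12 over the list alone, median −2.03, camera adjusted p = 0.202). Of the 38 interferon-stimulated genes 1 rose and 1 fell, and 36 did not pass (1 fell adjusted over the list alone, camera adjusted p = 0.724).

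The largest increases in shAdar1 were in the activin-binding protein follistatin (Fst, log2 fold change 3.16 ± 0.82), Abca8a (2.71 ± 0.27), the lysosomal protein precursor Psap (2.70 ± 0.13), the Notch effector Hes5 (2.68 ± 0.52), Adamts18 (2.67 ± 0.25), calretinin (Calb2, 2.60 ± 0.52), the mechanosensitive channel Piezo2 (2.44 ± 0.55) and Ormdl1 (2.37 ± 0.33). The largest decreases were in the iron exporter Slc40a1 (−3.93 ± 0.69), Wif1 (−3.32 ± 0.65), Dock5 (−3.17 ± 0.41), Ttn (−3.14 ± 0.36), Car10 (−2.92 ± 0.29), Dkk2 (−2.91 ± 0.70), Brinp3 (−2.63 ± 0.38) and Rgs13 (−2.57 ± 0.48). Several of these follow the control: Psap was at 74.6 ± 6.83 CPM in shControl1, below every other group, and differed by 0.01 ± 0.12 from shControl2, while Adamts18 was lower than in shControl2 (adjusted p = 0.00469), and Abca8a (−0.37 ± 0.24), Wif1 (0.93 ± 0.74) and Dkk2 (2.33 ± 0.94) did not pass there, with turned directions. Gad1 (1.45 ± 0.25) and the ephrin Efnb2 (0.99 ± 0.10) rose and the serotonin receptor Htr2c fell (−2.05 ± 0.23) against shControl1, with 0.31 ± 0.24, 0.05 ± 0.10 and −0.22 ± 0.23 against shControl2. In all 1380 genes were higher and 1020 lower, of which 274 and 294 were also called against shControl2, 404 were called the opposite way there, and 3 and 2 were called with both control hairpins pooled. Of the higher genes whose 3' UTR was searched, 300 of 1339 held TAATGAT, the word of genes lower in shControl1, against 176 expected. Counts without 1 sample were 493 to 917 higher and 291 to 640 lower, lowest without shControl1 replicate 2.

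The comparison of shAdar2 with shControl1 asked which sites depend on ADAR2. Coverage in shAdar2 replicate 2 allowed 105 sites to be tested. Of these, 17 sites in 10 clusters were edited less in shAdar2, and 1 was edited more. The mean level over the tested sites was 8.37% ± 0.168 against 13.8% ± 0.494 in shControl1. The site at chromosome X, position 71472201 went from 71.1% ± 5.48 (217 reads) to 2.24% ± 1.25 (179 reads), with an adjusted p of 1.36e-20, and stood at 46.0% ± 0.883 in shControl2. Chromosome 2, position 158210689 went from 67.4% ± 1.57 (690 reads) to 5.38% ± 4.66 (578 reads), with an adjusted p of 5.26e-21, and stood at 45.8% ± 2.55 in shControl2. The other large decreases were at chromosome 17, position 45799898 (58.4% to 5.71%), chromosome 3, positions 80496208 (70.9% to 19.2%, with 46.2% in shControl2) and 80510571 (43.6% to 5.36%), and chromosome 11, position 46086145 (35.9% to 5.64%). The increase was at chromosome 4, position 33106424 (1.46% to 12.2%), which was called against shControl2 too, but no increase was called without either shControl1 sample or without shAdar2 replicate 2. Of 86 sites tested against both controls, 16 were decreased against shControl1 and 12 against both.

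Interferon-stimulated genes rose in shAdar2 neurons, together with inflammatory genes, while cholesterol enzymes and several axon growth genes fell. Of the 38 interferon-stimulated genes 35 rose and 3 did not pass (36 rose adjusted over the list alone), with a median log2 fold change of 4.38, or 4.28 with genes listed at 0 in a group set to a floor of 3 counts over the group. The largest increases of all genes were Oasl2 (8.68 ± 0.83), Usp18 (6.85 ± 0.83), Ifi44 (6.80, SE 1.1), Isg15 (6.76 ± 1.21), Irf7 (6.37 ± 0.96), the chemokine Ccl20 (6.33 ± 0.95), Rsad2 (6.09 ± 0.73) and Parp14 (5.96 ± 0.79), from control values resting on 4 to 28 counts over both samples. Oasl2 was at 67.2 ± 57.0 CPM against 0.167 ± 0.145 CPM. Gbp2 (4.51 ± 0.40), Cxcl10 (4.47 ± 0.40) and Lgals3bp (4.27 ± 0.48) also rose. The camera adjusted p was 7.21e-08, and 0.724 with an estimated correlation. The list's median level per shAdar2 library was 5.99, 2.06 and 5.55 CPM in the technical libraries of replicate 1 and 16.3 CPM in replicate 2, against 0.252 to 0.802 CPM in the libraries of other groups. Inflammatory genes of the NF-kappaB list rose at 9 of 11 (9 over the list alone, median 1.66), among them Cxcl1 (4.69 ± 0.71) and Tnfaip3 (1.59 ± 0.24), with a camera adjusted p of 0.00455 and of 0.724 with an estimated correlation. Markers of microglia rose at 3 of 8 (5 over the list alone, camera adjusted p = 0.224), and endothelial, mural and fibroblast markers at 3 of 11 (3 over the list alone, median 0.34, camera adjusted p = 0.509).

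Cholesterol biosynthesis genes fell at 14 of 20 (14 over the list alone, median −1.23), among them Cyp51 (−1.69 ± 0.24) and the sterol carrier Stard4 (−2.21 ± 0.31), and both also fell against shControl2. Axon growth and guidance genes fell at 14 of 26 and rose at 3 (15 and 3 over the list alone, median −0.64), among them Stmn2 (−1.57 ± 0.12), Gap43 (−1.38 ± 0.14), Ncam1 (−1.30 ± 0.13) and Unc5c (−1.84 ± 0.19). By camera the adjusted p was 0.000159 for cholesterol and 0.0374 for axon growth, and 0.724 for both with an estimated correlation. The largest decreases of all genes were in Rgs13 (−4.33 ± 0.54), Spink10 (−4.22 ± 0.47), Dkk2 (−4.11 ± 0.73), Wif1 (−3.82 ± 0.66), Klhl14 (−3.79 ± 0.41), 1700020I14Rik (−3.61 ± 0.14), Lipo1 (−3.55 ± 0.34) and Ttn (−3.43 ± 0.36). Dkk2 (1.13 ± 0.97) and Wif1 (0.44 ± 0.73) did not pass against shControl2, where their direction turned. In all 3426 genes were higher and 3430 lower, of which 2244 and 2346 were also called against shControl2 and 390 were called the opposite way. Without shControl1 replicate 1 or 2, 2267 and 2224 genes were higher.

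**Figure D3:**
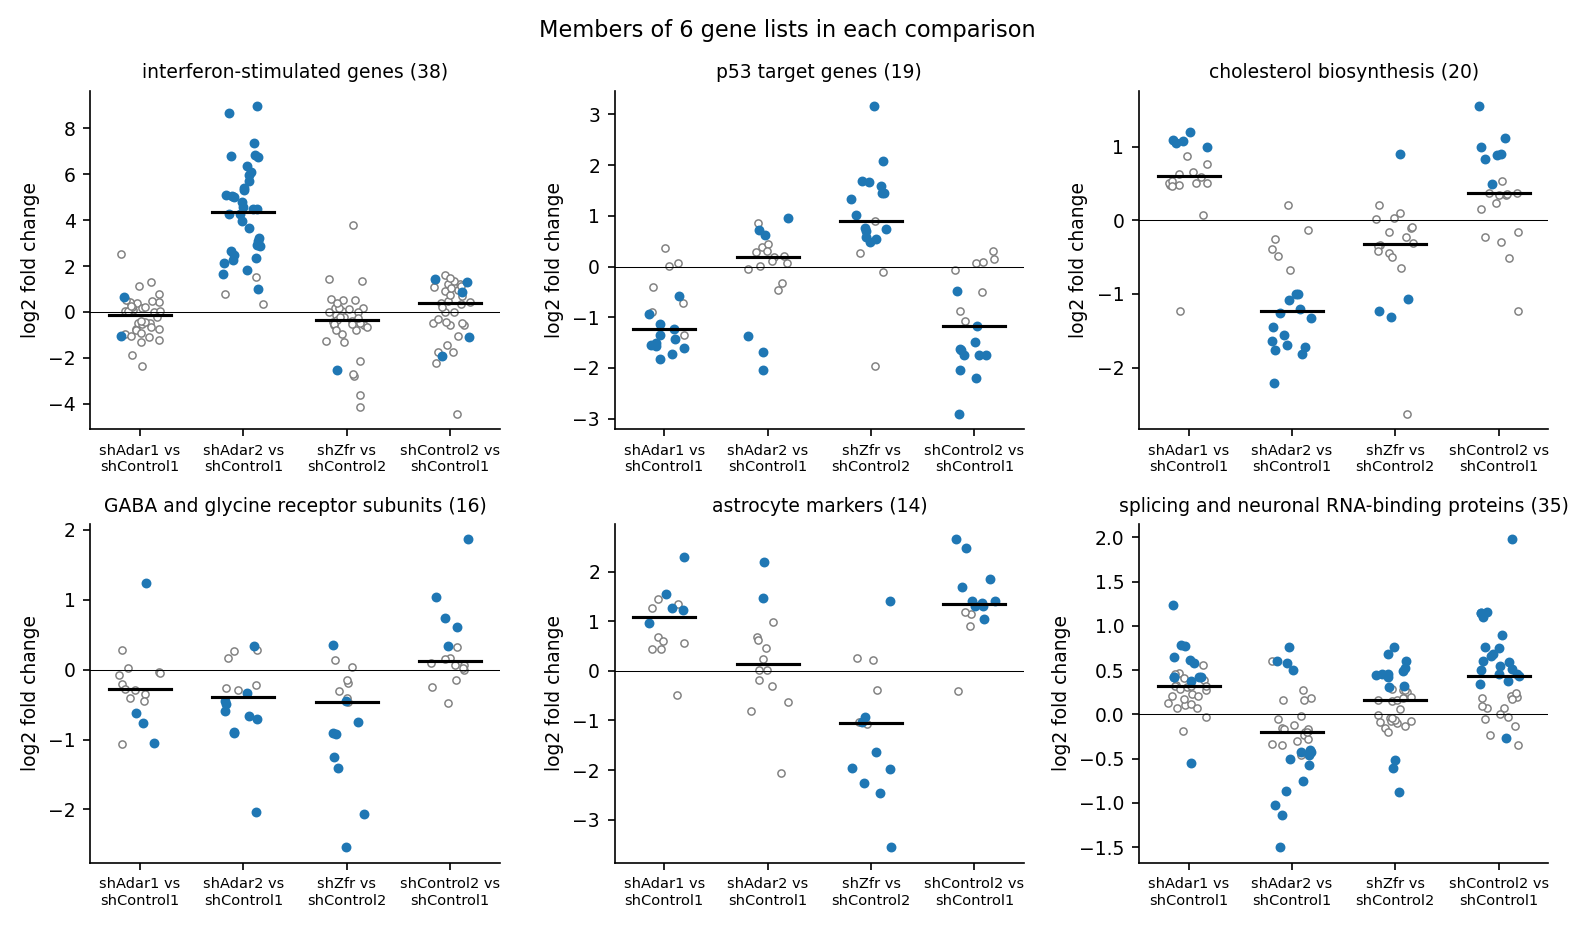
Log2 fold change of each tested member of 6 gene lists in the 3 knockdown comparisons and in shControl2 against shControl1. Each dot is a gene, filled where the adjusted p is under 0.05, and the bar is the median, which is 4.38 for interferon-stimulated genes in shAdar2 and has opposite signs for p53 targets in shAdar1 and shZfr.

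The comparison of shZfr with shControl2 asked which sites Zfr regulates. Editing was lower in shZfr at 161 of 1312 tested sites, in 108 clusters, and higher at 1. The mean level over the tested sites was 10.9% ± 0.144 against 16.2% ± 0.382 in shControl2. The site at chromosome X, position 71471989 went from 75.3% ± 5.77 (258 reads) to 27.3% ± 2.43 (233 reads), with an adjusted p of 4.28e-20. Chromosome 10, position 48964136 went from 80.9% ± 1.70 (131 reads) to 19.1% and 39.0% in the 2 shZfr samples (106 reads), with an adjusted p of 5.26e-11. The other large decreases were at chromosome 16, position 75121423 (65.3% to 16.7%), chromosome 10, position 48992582 (58.2% to 12.5%), and chromosome 12, positions 79618122 (47.8% to 5.57%) and 25745158 (75.9% to 33.8%). The increase was at chromosome 17, position 63402094 (1.35% to 21.5%), where shControl1 stood at 10.7% ± 1.01 and the site was not called against it or with pooled controls. Of 647 sites tested against both controls, 90 were decreased against shControl2, 295 against shControl1 and 86 against both. The count of decreased sites was 17 without shControl2 replicate 1 and 106, 93 and 97 without shControl2 replicate 2, shZfr replicate 1 and shZfr replicate 2.

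Genes of GABA and glycine receptors, postsynaptic proteins and ion channels, GABAergic interneuron markers and astrocyte markers fell in shZfr neurons, and p53 target genes rose. Among GABA and glycine receptor subunits 8 of 16 fell and 1 rose (10 and 1 adjusted over the list alone, median −0.46), led by Glrb (−2.54 ± 0.15), Gabra3 (−1.25 ± 0.18) and Gabra4 (−0.91 ± 0.13). Among postsynaptic proteins 8 of 18 fell and 1 rose (10 and 2 over the list alone, median −0.59), among them the scaffolds Dlg2 (−0.98 ± 0.13) and Homer1 (−0.92 ± 0.11) and the adhesion protein Nlgn3 (−0.91 ± 0.10). Glutamate receptor subunits, lower at 6 of 20 and higher at 3 (8 and 3 over the list alone), were not called by camera (adjusted p = 0.109). Voltage-gated channels fell at 10 of 23 (10 over the list alone, where 2 rose, median −0.31), among them Kcna2 (−0.84 ± 0.09) and Scn2a1 (−0.85 ± 0.10). Interneuron markers fell at 8 of 15 (9 over the list alone, median −0.74), among them Erbb4 (−1.23 ± 0.13), Lhx6 (−1.28 ± 0.24) and Gad2 (−1.21 ± 0.25). Astrocyte markers fell at 8 of 14 and rose at 1 (9 and 1 over the list alone, median −1.06), among them the glutamate transporter Slc1a2 (−2.47 ± 0.15), Gja1 (−2.26 ± 0.40) and Apoe (−1.96 ± 0.36). By camera the adjusted p was 0.000576 for GABA and glycine receptors, 0.00121 for postsynaptic proteins and for channels, 0.0042 for interneurons and 0.0024 for astrocytes. With an estimated correlation it was 0.285 for GABA and glycine receptors, 0.54 for channels and 0.854 for the other 3 lists. Against shControl1 the median turned to 0.10 for channels and to 0.03 for astrocytes, whereas Glrb (−1.93 ± 0.14), Gabra3 (−1.08 ± 0.18), Erbb4 (−1.69 ± 0.14) and Kcna2 (−0.39 ± 0.09) fell there too.

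Of the 19 p53 target genes 15 rose in shZfr (16 adjusted over the list alone, where 1 fell), with a median of 0.89. Zmat3 rose most, to 638 ± 4.95 CPM from 71.0 ± 1.15 CPM (3.17 ± 0.09, adjusted p = 4.1e-07), and Cdkn1a (1.44 ± 0.16), Trp53inp1 (1.44 ± 0.19) and Pmaip1 (1.66 ± 0.23) rose as well. The camera adjusted p was 3.61e-05, and 0.285 with an estimated correlation. Against shControl1 the list's median was −0.24, with Cdkn1a at −0.29 ± 0.16 and Pmaip1 at −0.54 ± 0.22, while Zmat3 (2.00 ± 0.09) and Trp53inp1 (1.51 ± 0.19) rose there too. The 3' UTR of Zmat3 holds both TCCCGTT and TAATGAT. The other largest increases were in Gpr50 (4.46 ± 0.42), the chloride channel Ano1 (3.70 ± 0.38), Ahnak (3.34 ± 0.23), Serinc2 (3.27 ± 0.37), the myosin light chain Myl12a (3.22 ± 0.34), the basement membrane protein Nid1 (2.96 ± 0.40) and Gdf1. Gdf1, which shares transcripts with Cers1 and is uncertain for that reason, had 807 counts in shZfr and was listed at 0 in shControl2, at least 309-fold higher with a floor of 3 counts over the group, and did not pass against shControl1 (0.60 ± 1.06).

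The largest decreases in shZfr were in the matrix protein Hapln1 (−5.47 ± 0.24), Gm2115 (−4.19 ± 0.65), Fgf1 (−4.00 ± 0.76), Fam107a (−3.64 ± 0.52), S100b (−3.56 ± 0.79), Vwa5b1 (−3.52 ± 0.43), neurogranin (Nrgn, −3.52 ± 0.32) and Thy1 (−3.50 ± 0.29). Hapln1 (−3.95 ± 0.24), Nrgn (−1.66 ± 0.31) and Thy1 (−2.19 ± 0.28) also fell against shControl1, where Vwa5b1 stood at 0.14 ± 0.47. Ilf2, another DZF-domain gene (0.85 ± 0.12), and the microprocessor subunit Dgcr8 (0.72 ± 0.10) rose, and the serotonin receptor Htr2c rose by 1.93 ± 0.23 but stood at 0.10 ± 0.21 against shControl1. In all 2464 genes were higher and 2078 lower, of which 1176 and 1160 were also called against shControl1 and 407 were called the opposite way, and without 1 sample 942 to 1336 were higher and 924 to 1268 lower. The gene tests of all comparisons share 1 estimate of the spread over the 10 samples. A pair of unusually alike samples can therefore lower it for every comparison. With only the groups compared in a fit, and so fewer samples, shAdar1 had 910 higher and 783 lower genes and shAdar2 1950 and 2097. The 2 shZfr samples differed by little more than sampling noise (0.894% of genes past a chi-square test, against 39.6% to 68.1% for other pairs of libraries). They were kept as 2 samples because the labels call them biological replicates, but if they are 1 culture the p-values of this comparison rest on 1 knockdown sample, and summing them to 1 left 1077 higher and 932 lower genes and 151 decreased sites.

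To ask whether Zfr acts on the sites of each ADAR, site lists were compared. Sites that lost editing in shAdar2 mostly lost it in shZfr: 12 of the 16 shAdar2-decreased sites among 69 tested in both were also decreased in shZfr, against 3.71 for independent lists (odds ratio 33.2, Fisher's exact p = 2.86e-07). Over all 69 sites the changes correlated (Pearson's r = 0.84, Spearman's rho = 0.64). Sites of a cluster are not independent, and the 16 shAdar2-decreased sites lay in 10 clusters. The Fisher's tests of overlap count sites singly, so their p-values can be too small. Sites that lost editing in shAdar1 showed no such overlap: 21 of 222 were decreased in shZfr among 577 tested in both, against 34.2 for independent lists (odds ratio 0.44, p = 0.00194), and with lists from Fisher's test on pooled reads the overlap was 40 against 39.2 (odds ratio 1.04, p = 0.907), so that the shortfall was lost, while at a minimum of 10 reads it was 36 against 51.2 (odds ratio 0.57, p = 0.00548) and at 50 reads 14 against 11.8 (odds ratio 1.55, p = 0.375). The shAdar1-decreased and shZfr-increased lists shared 1 site (Fisher's exact p = 0.385). The lists of shAdar1 and shAdar2, which share control samples, had 3 sites in common of 27 and 17 among 92, against 4.99 for independent lists, which lists with shared controls are not, so this count decides nothing.

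Sites tested in all 3 comparisons were then set against each other by class. Classes follow the calls, so "only" means not called in the other knockdown. All sites decreased only in shAdar2 were lower in shAdar1 too, by −0.415 to −16.6 percentage points. Those decreased only in shAdar1 changed by −8.00 to 16.1 in shAdar2, in both directions. The shAdar1 site test missed most simulated changes, so these classes cannot be taken as sites of 1 enzyme. In shZfr the editing level changed by −2.51 percentage points (SD 6.51) at 23 sites decreased only in shAdar1 and by −15.0 (SD 12.6) at 13 sites decreased only in shAdar2, a difference of 12.5 percentage points. A two-sided exact permutation over clusters, each given the class of most of its sites (15 and 6 clusters), gave p = 0.0143. Some clusters hold sites of both classes, so the difference tested is not exactly that over sites. On the log2 odds scale the difference was 1.94 (same exact permutation test, p = 0.00024). The 29 sites decreased in neither changed by −2.51 percentage points, like those decreased only in shAdar1, and the 3 decreased in both by −24.9. Mean log2 odds changed by −0.279 (shAdar1 only), −2.22 (shAdar2 only), −2.10 (both) and −0.995 (neither). As background, sites decreased only in shAdar1 and only in shAdar2 changed in shControl2 against shControl1 by −5.68 (SD 5.68) and −9.36 (SD 6.63) percentage points. The summed editing level over 499 sites covered in all samples was 5.59% ± 1.13 in shAdar1, 7.86% ± 0.287 in shAdar2 and 5.77% ± 0.988 in shControl1, and 3.03% ± 0.00817 in shZfr against 3.93% ± 0.557 in shControl2. The mean of the site levels was 1.66% ± 0.265 in shAdar1, 1.91% ± 0.0361 in shAdar2 and 2.99% ± 0.0966 in shControl1, and 1.31% ± 0.0194 in shZfr against 2.17% ± 0.0415 in shControl2. For shAdar2 the 2 measures differ in direction, and exact permutation tests of 2 against 2 samples cannot go below p = 0.333. The summed level weighs sites by reads, so it also moves with the share of reads at deep sites. The deepest site held 12.3% and 14.7% of these reads in shAdar2, against 7.07% and 7.51% in shControl1. Without it the summed level was still higher in shAdar2 (5.84% and 6.05%, against 4.20% and 5.20%).

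**Figure D4:**
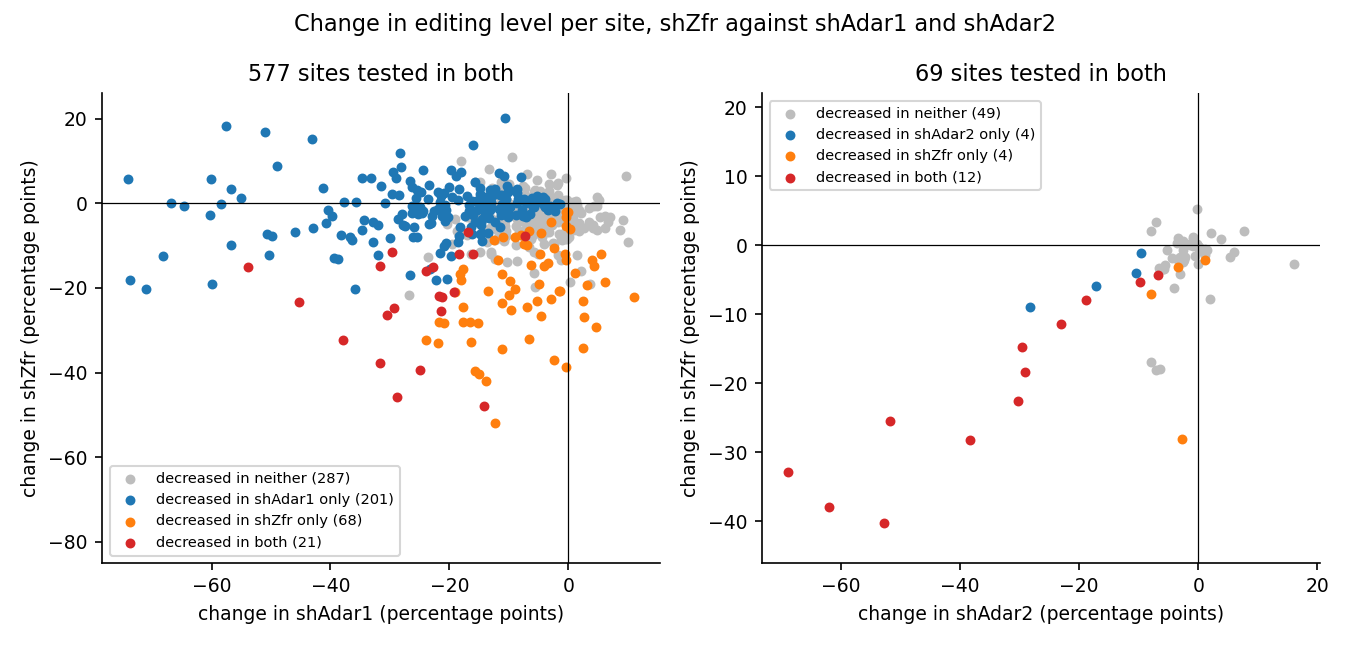
Change in editing level in percentage points at each site tested in both comparisons, in shZfr (vertical axis) against shAdar1 (left) and shAdar2 (right), coloured by the comparison in which the site was decreased. Of 16 sites decreased in shAdar2, 12 were decreased in shZfr, and of 222 sites decreased in shAdar1, 21 were.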

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

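The alternatives with the other or pooled control hairpins, summed shZfr samples, no Rn45s, no deepest site and the block within shAdar1 and shControl1 were chosen after seeing the data. Of 1609 values of named genes 1465 kept their direction and their side of the threshold, as did 365 of 439 medians of gene lists, 216 of 241 values of named sites and 110 of 207 counts, levels and overlaps. For the 37 other medians of lists, which the text does not report and no setting that turned them called, 55 of 410 values turned. Among named genes and gene lists the choice of control moved more values than any other alternative. The tests of the difference between the control hairpins bear on why without settling it. Counts of decreased sites moved further with all 5 groups in 1 fit, which tests fewer sites (31 in shAdar1 and 13 in shZfr). For other changes the cause was not tested unless one is named. With the other control hairpin shAdar1 had 2860 higher and 2049 lower genes, shZfr 3459 lower genes, and 135 (shAdar1) and 422 (shZfr) decreased and 7 (shAdar2) increased sites. Log2 changes turned there in shAdar1 for Adarb1 (0.16), Zfr (−0.58), Abca8a (−0.37), Adamts18 (−1.10), Piezo2 (−0.95), Wif1 (0.93), Dkk2 (2.33), Phlda3 (0.31), Cdkn1a (0.18), Sesn2 (0.30), Bbc3 (0.21) and Aldoc (−0.35), in shAdar2 for Dkk2 (1.13) and Wif1 (0.44), and in shZfr for Adar (−0.34), Adarb2 (0.51), Vwa5b1 (0.14), Cdkn1a (−0.29) and Pmaip1 (−0.54). Medians turned in shAdar1 for splicing (−0.0430), glutamate receptors (−0.29), channels (−0.32), p53 (0.18), astrocytes (−0.20), progenitors (−0.25) and immediate early genes (0.35), in shAdar2 for astrocytes (−1.31), oligodendrocytes (−1.10) and interneurons (−0.11), and in shZfr for glutamate receptors (0.12), cholesterol (0.19), channels (0.10), p53 (−0.24), excitatory markers (0.57) and astrocytes (0.0329). With pooled controls shAdar1 had 3 higher and 2 lower genes, shZfr 892 and 995, decreased sites in shAdar1 were 139 and increased sites 1 in shAdar1 and 0 in shZfr. Zfr (−0.27), Adamts18 (−0.19), Piezo2 (−0.0696) and the medians of channels (−0.19) and glutamate receptors (−0.14) turned in shAdar1, those of astrocytes (−0.73), oligodendrocytes (−0.35) and endothelial, mural and fibroblast markers (−0.19) in shAdar2, that of excitatory markers (0.26) in shZfr, and Adar (−0.14) and Adarb2 (0.21) in shZfr. Pooling adds the difference between the controls to the spread. Fits of only the groups compared gave 910 higher genes in shAdar1, 1950 higher and 2097 lower in shAdar2, and 3854 and 4055 in shZfr, since each then has its own estimate of the spread, and the interferon median in shAdar1 turned (0.0190). Replicate numbers did not pair the samples (correlations of deviations −0.12, −0.10 and 0.08 in the 3 comparisons). With the replicate block genes were 1350 higher and 992 lower in shAdar1, 3383 and 3444 in shAdar2 and 2475 and 2089 in shZfr, increased sites fell to 1 in shAdar1 and 0 in shAdar2, and control sites to 6. The block within shAdar1 and shControl1 gave 807 and 605 genes, and crossed numbers 1469 and 1216. Summing the shZfr samples left 1077 higher and 932 lower genes. Technical libraries 1-2 and 1-3 alone left 0 increased sites in shAdar2, and with 1-2 the interneuron median turned (−0.21). At a minimum of 10 reads, which tests more sites, shAdar1 had 720 decreased sites and shAdar2 73, with 4 increased, the summed level in shAdar2 differed by 1.16 percentage points, and the overlaps were 36 (shAdar1 and shZfr), 34 (shAdar2 and shZfr) and 25 (shAdar1 and shAdar2). At 50 reads, which tests fewer, decreased sites were 79 in shAdar1, 3 in shAdar2 and 50 in shZfr, increased sites 1, 0 and 0, control sites 45, the overlaps 0 (shAdar1 with shZfr-increased), 3 (shAdar2 and shZfr) and 1 (shAdar1 and shAdar2), and the class difference 13.9 points (exact permutation p = 0.0667, the smallest possible). All 5 groups in 1 fit, with fewer sites, left 31 decreased sites in shAdar1, 13 in shZfr, 2 increased in shAdar2, 0 in shZfr and 6 between controls. Fisher's test on pooled reads, which leaves out the spread between samples, called 134 control sites, and its lists shared 40 (shAdar1 and shZfr) and 12 (shAdar1 and shAdar2) sites. The mean of site levels changed by −1.33 in shAdar1 and −1.09 in shAdar2, and without the deepest site the summed level in shAdar2 differed by 1.25. Leaving out single samples gave 493 to 917 higher and 291 to 640 lower genes in shAdar1, 2224 to 3843 higher in shAdar2, 942 to 1336 higher and 924 to 1268 lower in shZfr, and 3574 to 5163 between controls. It gave 35 to 170 decreased and 0 to 0 increased sites in shAdar1, 0 to 1 increased in shAdar2, 17 to 106 decreased and 0 to 2 increased in shZfr, and 0 to 8 between controls, and Adarb2 in shAdar1 ran from −0.48 to 0.14 and Adar in shZfr from −0.0318 to 0.20. Medians that turned ran from −0.49 to 0.0399 (interferon) and −0.0671 to 0.0864 (channels) in shAdar1, from −0.13 to 0.43 (interneurons), −0.32 to 0.50 (astrocytes) and −0.21 to 1.68 (oligodendrocytes) in shAdar2, and from −0.15 to 0.0446 (excitatory markers) in shZfr. A lone sample in these fits is assumed to vary like the others.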

Other observations

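The tests of scaling, of the microglia share per library, of a lower Adarb1 level, of a single shAdar2 sample and of the shControl2 word were chosen after the results they bear on had been seen, as was the size of 2 standard errors asked of a difference between groups in the word test.

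Some genes of other groups changed in shAdar2, although camera called none of the lists named here (adjusted p = 0.0531 to 0.686). Postsynaptic protein genes rose at 10 of 18 and fell at 2 (11 and 2 adjusted over the list alone, median log2 fold change 0.44, camera adjusted p = 0.0791), among them the kinase gene Camk2a (1.85 ± 0.26). Genes of double-stranded RNA-binding and DZF-domain proteins fell at 8 of 17 and rose at 2 (10 and 2 over the list alone, median −0.31, camera adjusted p = 0.0791), among them Strbp (−1.60 ± 0.13) and Prkra (−1.11 ± 0.13). Marker genes of excitatory neurons moved apart (15 tested, median −0.39): the glutamate transporter Slc17a7 rose (2.14 ± 0.17) and the transcription factor Neurod6 fell (−1.99 ± 0.19). Interneuron markers did so too (15 tested, median 0.15), with Gad1 higher (1.97 ± 0.25) and Npy lower (−3.28 ± 0.45). Among known editing targets 11 of 30 fell and 4 rose (11 and 5 over the list alone, camera adjusted p = 0.347), including the receptor gene Bmpr2 (−1.90 ± 0.15). GABA and glycine receptor genes fell at 9 of 16 and rose at 1 (9 and 1 over the list alone, median −0.39, camera adjusted p = 0.0531), including Glra2 (−2.04 ± 0.12). The 9 genes named in this paragraph moved the same way against shControl2.

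Replicate libraries differed in how alike they were. The technical libraries of shAdar2 replicate 1, prepared from RNA of the same neurons, had 57.6% to 68.1% of genes past a chi-square test, and Adarb2 stood at 154.5, 54.3 and 145.2 CPM in them. The pairs of shControl1, shControl2 and shAdar1 samples had 50.3%, 39.6% and 48.0%, and the shZfr pair 0.894%. The site at chromosome 17, position 39980697 alone held 5.49% to 14.7% of the reads at sites covered in all samples. Its share was highest in shAdar2 (12.3% and 14.7%), where its level was 20.6% and 19.7%, against 16.6% and 22.2% in shControl1. In shAdar1 its level was 23.6% and 15.9%, so neither knockdown clearly lowered it. Whether its G reads come from ADAR editing was not tested.

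The difference between the control hairpins, 6367 genes, is larger than that between shAdar1 and either of them. Other size factors and the removal of Rn45s left at least 6369 genes, which argues against the choice between these settings as the source. With DESeq2 size factors the split moved from 2937 higher and 3430 lower to 3160 and 3210. Both kinds of size factors take most genes as unchanged, so an error of scaling common to both cannot be seen this way. The difference between the 2 shAdar1 samples, which runs along glial and dividing-cell genes, accounted for 0.645% of the variance. That share lies under the bound set beforehand as counting against a shift in such cells. A difference between 2 replicates holds noise at all other genes, so a low share cannot decide this. Over 37 listed glial and progenitor genes the control hairpins differed by a median of 1.41, and such a shift stays open. A candidate explanation is that each hairpin lowers transcripts that match its seed: the excess of TCCCGTT in genes lowest in shControl2 was 11.1 standardised units (40 random sets reached 5.70), and genes with that word that were not used to find it were lower in shControl2 by 10.8 standard errors (ratio −10.8), although 169 of the 3325 genes lower there than in shControl1 held it (78.2 expected), so matches to it cover few of them. For shControl1 the excess of TAATGAT was 8.59 units (random sets reached 5.31), and unused genes with it were lower there (ratio −6.86), but they were lower still in shAdar2, the outcome set beforehand as counting against this explanation, by 1.34 standard errors, under the 2 taken afterwards as its spread. It therefore cannot be told apart from other differences for shControl1, the hairpin sequences are not given in the sources used here, and culture or virus batches that follow the hairpin stay open for both. Words marked knockdown groups too: unused genes with TCCAAGT were lower in shAdar2 (ratio −11.3) and those with GTTGCAC in shZfr (ratio −9.47). The ratio was −1.57 for ATACTGC in shAdar1. TCCAAGT was in 713 of 3302 genes lower in shAdar2 (517 expected) and GTTGCAC in 296 of 1982 lower in shZfr (144 expected). TCCCGTT was in 175 of 2401 genes higher in shZfr (81.8 expected). Seed effects in the knockdown comparisons therefore stay open.

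The rise of interferon-stimulated genes in shAdar2 may reflect a response to the hairpin, its virus or lower ADAR2, and the following was tested. A single library is not clearly set aside by the bound set beforehand, because technical library 1-2 had 28 of 38 genes above all libraries of other groups, fewer than that bound asked for, but with either shAdar2 sample left out or 1 technical library for replicate 1 the list's median stayed at 3.30 or more. Microglia stay open: their listed markers had a median of 0.757 CPM in shAdar2, 7.12% of that of the interferon-stimulated genes and under the bound set beforehand, but by library, a split made afterwards, the replicates lay on both sides of it (12.7% to 27.4% in the technical libraries of replicate 1 and 4.91% in replicate 2), and 3 of the 8 rose. A lower Adarb1 level alone is argued against, since Adarb1 differed by 0.0844 ± 0.120 between shAdar2 and shZfr while the list differed by a median of 4.74. What is specific to this hairpin or its virus preparation follows the group and stays open, as does, untested, an effect of ADAR2 loss that transcript levels do not show.

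Among the 69 sites tested in both comparisons, 12 of the 16 that lost editing in shZfr also lost it in shAdar2. Calls were permuted within 6 strata of shControl2 level and of coverage in shControl2 and shZfr. This gave 6.83 shared sites on average against 12 observed (one-sided permutation test, p = 3.00e-05), which argues against level and coverage only as far as these strata hold them alike. The strata are coarse: sites decreased in shAdar2 had a median level of 25.4%, against 3.82% at the others. Level within a stratum therefore stays open. Single sites rather than clusters were permuted, so this p-value can be too small. A candidate explanation is the lower Adarb1 level in shZfr. Over the 16 sites decreased in shAdar2, the change of log odds in shZfr was 0.559 of that in shAdar2 (95% bootstrap interval over clusters 0.444 to 0.697). The slope met the bound set beforehand, but the lower end of its interval did not. Adarb1 itself changed by −1.02 in shZfr and −1.26 in shAdar2, each against its own control. How editing scales with Adarb1 was not measured, so the slope goes with this explanation without deciding it. The word GTTGCAC, held by 129 of 774 genes lowest in shZfr against 48.1 expected, had 0 matches in the longest annotated 3' UTR of Adarb1. This was the outcome set beforehand as counting against a direct effect of that hairpin on Adarb1 through its seed. It covers that word and that 3' UTR only. The hairpin sequence is not given, so whether the word matches its seed is not known, and such an effect stays open. Zfr also fell in shAdar2 (188.2 CPM, against 172.6 CPM in shZfr), so whether Zfr acts on these sites beside Adarb1 in both groups stays open, and editing at the same sites was also lower in shControl2 than in shControl1.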
